A study of Homo sapiens with 4 samples.

How the data were processed

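Gene expression was measured in HT29, a human colorectal cancer cell line, on 4 one-colour Agilent arrays labelled with Cy3. Each array held total RNA from a different culture after 24 h with DMSO, tretinoin, encorafenib plus binimetinib, or all 3 compounds. Per the labels, the doses were 0.1% DMSO, 1 µM tretinoin, 10 µM encorafenib and 10 µM binimetinib. Per the file headers, the array design was 072363 and the scanned images were read by Agilent Feature Extraction 10.7.3.1 with protocol GE1_107_Sep09. The deposited scanner files hold the intensity of each spot on a linear scale, after background subtraction and detrending by that program and before any scaling between arrays. The authors also deposited a table of log2 values for 32996 probes. Its columns differ from the log2 spot values by 1 constant per array, and each probe is centred on its median over the 4 arrays. Its header gives a filter by the authors on raw signal from 10.0 upwards.

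Each array carried 62976 spots, of which 60901 were not controls. These held 58201 distinct probes, and 300 of the probes were spotted 10 times each. Probe names came from the RefSeq accessions that the files pair with probes, looked up in a RefSeq gene table of assembly GRCh38.p14, which was used for names only. This named 34982 probes by accession. A further 1794 were named by the authors' symbol, 127 by that symbol brought up to date, and 1439 by a symbol absent from the table. The remaining 19859 probes had no gene name. The array design was annotated on GRCh37, so no coordinates are given.

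The main values were the log2 processed signal minus the 75th percentile of the array. Spots of a probe were averaged without spots that the scanner software marked as outliers, and each of the 26797 genes was represented by its probe with the highest mean over the 4 arrays. A gene entered a comparison if it was well above background, as the scanner software calls it, on at least 1 of the 2 arrays. Where the other array was not well above background, its value was replaced by the higher of itself and the lowest signal among probes well above background on that array. Such a difference is a bound and is written as "at least". The difference between the tretinoin responses with and without the inhibitors was computed only for the 16030 genes well above background on all 4 arrays. No spot was saturated.

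The groups have 1 array each, so there are no replicates, no p-value is given, and the number of arrays limits the precision. A fit with additive effects of tretinoin and the inhibitors would leave 1 residual degree of freedom; it was not run, because it takes the difference between the tretinoin responses, the question of the study, as error. Genes were counted as higher or lower at 2-fold, a log2 difference of 1. The only error available is technical. From 275 repeatedly spotted probes above background, the standard deviation (SD) of a log2 difference between 2 arrays was between 0.07 and 0.08 (0.0692 for tretinoin vs DMSO, 0.0776 for tretinoin added to the inhibitors), and 0.104 for the difference between the tretinoin responses. It does not cover differences between cultures, RNA preparations or labelling reactions. Different probes of a gene differed more, with an SD of 0.24 for tretinoin vs DMSO and 0.40 for the inhibitors vs DMSO over 4426 genes. The 4 arrays lay on 1 slide and were read in 1 scan session, so the position on the slide and the group cannot be told apart.

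The genes named by size were the 10 highest and the 10 lowest of each comparison among genes with a standard symbol, measured on both arrays and outside the dimmest 25% by level. Some genes that this rule takes are not reported here. A total of 25 gene lists with 410 entries, 406 of them on the array, were written down together with that rule and the comparisons before the data were examined. They covered retinoic acid response, retinoid metabolism and RXR, ERK pathway output, the EGFR family and its ligands, DNA replication and S phase, mitosis, cell cycle inhibitors, MYC and ribosome biogenesis, pro-apoptotic and anti-apoptotic BCL2 family members, death receptors and caspases, and p53 targets. They also covered enterocyte genes, goblet and enteroendocrine genes, Wnt targets and crypt stem cell genes, interferon response, antigen presentation, NF-kB and chemokines, unfolded protein and integrated stress response, cholesterol synthesis, NRF2 targets, AHR and PXR targets, epithelial-mesenchymal transition, non-epithelial cell markers and housekeeping genes. The median log2 difference of a list was placed among the medians of 10000 random lists of as many genes, matched for level in 20 bins. A list is said to stand apart below percentile 2.5 or above percentile 97.5. Members of a list are not independent, so the percentile describes these arrays and is not a test of the treatment.

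The steps were tested on simulated arrays made from the DMSO array with the technical error of tretinoin vs DMSO, in a step with 17289 genes. Of 50 genes simulated at each of 1.5-fold, 3-fold, 4-fold and 8-fold, 0 were counted at 1.5-fold and 50 at each of the other sizes. None of the 16792 genes simulated without a difference was counted. The simulated noise was that of repeated spots only, so small beside 2-fold that these counts were set in advance. Differences between cultures or between probes were not simulated, so the counts give no rate of false calls for the real arrays. All 20 lists simulated with a shift lay above percentile 97.5, and 4.0% of 200 lists without a shift fell outside the range. The simulated shift was larger than some list medians said to stand apart below.

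There were 8 alternatives chosen in advance: normexp background correction with an offset of 50, quantile normalization, scaling by the median of detected probes, scaling by the E1A spike-in probes, a filter asking both arrays to be above background, no filter, the mean of all probes of a gene, and the authors' table. The normexp correction used the median brightness of the spot and of its local background, because the files hold no mean brightness. After the data were seen, 1 more was added, which left out spots whose local background was at least 1.5 times the median of their array. A fit with the slide as a block was not run, since there was 1 slide. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.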

Results

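HT29 is a colorectal cancer cell line with an activating mutation of the kinase BRAF. Expression was measured on 4 arrays, 1 each for the vehicle DMSO, for the retinoid tretinoin, for the inhibitor pair encorafenib/binimetinib and for the 3 compounds together. Tretinoin is all-trans retinoic acid, the ligand of the retinoic acid receptors. Encorafenib inhibits BRAF and binimetinib inhibits MEK, the kinases upstream of ERK. The DMSO array had 31029 spots well above background (50.95% of 60901), the tretinoin array 29621 (48.6%), the encorafenib/binimetinib array 31797 (52.2%) and the array with all 3 compounds 30773 (50.5%). The median coefficient of variation of repeated spots lay between 2.86% and 3.06% per array. No group had a replicate. Each fold below is the ratio of 2 arrays, or of 2 such ratios for the difference between the tretinoin responses. Differences between cultures are part of each fold and were not measured, and the only error known is technical.

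Tretinoin was first compared with DMSO, which shows the response to the retinoid alone. Outside the dimmest 25% of genes above background on both arrays, genes of the retinoic acid pathway were among the highest. CYP26A1, which breaks down retinoic acid, was 63.4-fold higher (log2 difference 5.99). Its DMSO signal of 22.9 was near 10.6, the lowest signal well above background on that array, so the size of this fold is uncertain. STRA6, the cell surface receptor that takes up retinol, was 15.1-fold higher. RARRES1, a gene known for its retinoid response, was higher by 3.41 on the log2 scale, and DHRS3, which reduces retinaldehyde to retinol, was 7.86-fold higher. The nuclear receptor NR0B2 was 14.5-fold higher, the hormone FGF19 6.98-fold and the sterol 27-hydroxylase CYP27A1 6.42-fold. The remaining genes named by size on the higher side were the kinase TXK (6.62-fold), the ubiquitin ligase TRIM31 (6.58-fold) and RAMP1, a partner of the calcitonin receptor family (6.40-fold).

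On the lower side, the Wnt ligand WNT11 was 4.65-fold lower with tretinoin and ASCL2, a transcription factor of intestinal stem cells, 4.16-fold lower. The water channel AQP1 was 4.48-fold lower, with a log2 difference of −0.80 in its other probe, the scaffold protein PDZK1 4.08-fold, the trefoil peptide TFF2 3.99-fold and cytidine deaminase, CDA, 3.93-fold. CLIC3 was 3.81-fold lower, LY6D 3.40-fold and IGFL2 3.40-fold. In all, 241 of 17478 genes were at least 2-fold higher, 42 of them as bounds, and 163 were at least 2-fold lower, 50 of them as bounds. At 4-fold, 29 genes were higher and 12 lower. The share of higher genes among these depended on the scaling: 59.7% as reported, 94.0% when the arrays were scaled by the E1A spike-in probes (778 higher and 50 lower) and 75.5% with the normexp background correction (105 higher and 34 lower). The majority turned with the authors' table, which gave 316 higher and 353 lower (47.2% higher), and without a filter on dim genes, which gave 829 and 850 (49.4%). The counts from the authors' table used values below background as they were, without bounds. The spike-in scaling moved the median of all genes by 0.42 (log2).

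Among the gene lists, 8 of the 14 measured retinoic acid response genes were at least 2-fold higher and none lower, with a median log2 difference of 1.02 at percentile 100. Besides the genes above, PLAAT4 was 3.88-fold higher, the nuclear receptor cofactor NRIP1 2.03-fold and TNFAIP2 2.02-fold. The interferon response list had a median of 0.49 (percentile 100) although only 1 of its 26 measured genes, the transcription factor IRF1, was 2-fold higher (2.33-fold). Antigen presentation had a median of 0.47 (percentile 100), with 3 of 12 genes higher: the immunoproteasome subunits PSMB9 (3.79-fold) and PSMB8 (2.47-fold) and the peptide transporter TAP1 (2.02-fold). NF-kB and chemokine genes had a median of 0.31 (percentile 99.95) with 0 of 13 past 2-fold; ICAM1 had a log2 difference of 0.91 and BIRC3 of 0.86. DNA replication genes (median 0.20, percentile 100) and mitosis genes (0.14, percentile 99.8) stood apart on the higher side by small amounts, with none of 24 genes in either list past 2-fold.

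Goblet and enteroendocrine genes stood apart on the lower side with a median of −0.44 (percentile 0), and 2 of 11 were at least 2-fold lower: TFF2 and REG4 (2.23-fold). Without a filter on dim genes that median was 0.018. Wnt targets and crypt stem cell genes had a median of −0.19 (percentile 0.21), which became 0.24 with spike-in scaling, and 3 of 15 were lower: ASCL2 and the Wnt feedback inhibitors AXIN2 (2.53-fold) and NKD1 (2.18-fold). The other lists did not stand apart. Their medians were 0.04 for retinoid metabolism and RXR, 0.10 for ERK pathway output, 0.06 for the EGFR family, −0.02 for cell cycle inhibitors, −0.03 for MYC and ribosome biogenesis, −0.06 and 0.10 for pro-apoptotic and anti-apoptotic BCL2 members, 0.13 for death receptors and caspases, and −0.02 for p53 targets. They were 0.08 for enterocyte genes, 0.09 for the unfolded protein and integrated stress response, −0.06 for cholesterol synthesis, −0.07 for NRF2 targets, −0.14 for AHR and PXR targets, −0.04 for epithelial-mesenchymal transition, −0.12 for non-epithelial markers and 0.01 for housekeeping genes.

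Encorafenib/binimetinib was compared with DMSO to give the response to BRAF and MEK inhibition, on which the tretinoin response with inhibitors rests. The ERK pathway output list was the lowest of the 25 lists: 16 of its 18 measured genes were at least 2-fold lower and none higher, with a median of −2.13 (percentile 0). FOSL1, an AP-1 subunit, was 13.7-fold lower, the ERK phosphatase DUSP6 10.3-fold, the transcription factor ETV5 7.71-fold, the feedback inhibitor SPRY4 5.83-fold, MYC 4.95-fold and cyclin D1, CCND1, 3.29-fold. DNA replication and S phase genes had a median of −1.40 (percentile 0), with 21 of 24 lower, among them MCM10 (5.28-fold), CDC6 (4.88-fold) and CCNE1 (3.59-fold). Mitosis genes were less far below DMSO, with a median of −0.70 (percentile 0) and 4 of 24 past 2-fold, including PLK1 (2.22-fold) and AURKB (2.14-fold). MYC targets of ribosome biogenesis had a median of −1.47 (percentile 0), with 13 of 16 lower, such as BOP1 (4.51-fold) and RRP12 (3.73-fold). With spike-in scaling the medians were −0.82 for DNA replication, −0.12 for mitosis and −0.89 for ribosome biogenesis.

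Several lists were higher with the inhibitors. In the interferon response list 15 of 26 genes were at least 2-fold higher and none lower, with a median of 1.17 (percentile 100); IFI44L was 10.4-fold higher, MX2 5.67-fold and MX1 4.78-fold, while IRF1 had a log2 difference of 0.03. Cell cycle inhibitors had a median of 0.51 (percentile 99.98) with 4 of 16 higher: BTG2 (11.6-fold), CDKN1C (7.73-fold), TXNIP (4.58-fold) and BTG1 (2.10-fold). Antigen presentation had a median of 0.37 (percentile 99.9), with PSMB9 2.68-fold and PSMB8 2.26-fold higher. Enterocyte genes had a median of 0.45 (percentile 98.96), with 5 of 14 higher, among them the peptide hormone GUCA2A (10.5-fold), FABP1 (7.96-fold) and the intestinal transcription factor CDX2 (2.79-fold), and 1, CEACAM1, 2.05-fold lower. Retinoic acid response genes also stood higher without added tretinoin (median 0.45, percentile 99.85), with 5 of 14 past 2-fold, such as STRA6 (8.46-fold), RARRES1 (6.97-fold) and PLAAT4 (4.42-fold), and TGM2 6.76-fold lower. AHR and PXR targets had a median of 0.56 (percentile 99.5), with CYP1A1 8.05-fold and AHRR 2.99-fold higher. Goblet genes did not stand apart as a list (median 0.24, percentile 89.0), but 4 of 11 were higher, with SPINK4 at 16.6-fold, TFF3 at 12.0-fold, FCGBP at 7.39-fold and REG4 at 6.70-fold.

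Outside the dimmest 25% of genes above background on both arrays, the highest genes with the inhibitors were the selenium carrier SELENOP (26.1-fold), the ectonucleotidase ENTPD8 (24.3-fold), the protease CAPN9 (22.6-fold), the sialyltransferase ST6GALNAC1 (21.2-fold), the pro-apoptotic BCL2 member BMF (20.9-fold), COXFA4L3 (20.1-fold), KLK12 (19.6-fold), TP53INP1 (18.2-fold), ATP6V1B1 (16.6-fold) and, as the last of the 10, the trypsin inhibitor SPINK1. The lowest of these besides FOSL1 and DUSP6 were MYEOV (12.7-fold), TNS4 (12.6-fold), the claudin CLDN2 (10.8-fold), NNMT (10.5-fold), ADAM19 (10.2-fold), HAT1 (9.69-fold), FJX1 (9.27-fold) and the long noncoding RNA CCAT1 (8.81-fold). The HAT1 spot of the encorafenib/binimetinib array lay in a patch with a local background 2.68 times the median of the array, and HAT1 had no other probe. As a bound, FGF19 was at least 66.6-fold lower. In all, 1664 of 18197 genes were at least 2-fold higher and 1226 lower. The higher share was 57.6%, against 93.3% with spike-in scaling (4175 higher and 300 lower), which moved the median of all genes by 0.58 (log2), and 49.1% with the normexp correction (768 higher and 797 lower).

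The lists that did not stand apart with the inhibitors were retinoid metabolism and RXR (median 0.24), the EGFR family (0.07), pro-apoptotic BCL2 members (−0.36, with a mean of 0.31), anti-apoptotic BCL2 members (0.03), death receptors and caspases (−0.06, with a mean of 0.15) and p53 targets (0.13). Nor did Wnt and stem cell genes (0.19), NF-kB and chemokines (−0.28), the stress response (−0.04), cholesterol synthesis (−0.15), NRF2 targets (−0.25), epithelial-mesenchymal transition (0.00), non-epithelial markers (0.07) and housekeeping genes (−0.26).

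**Figure D1:**
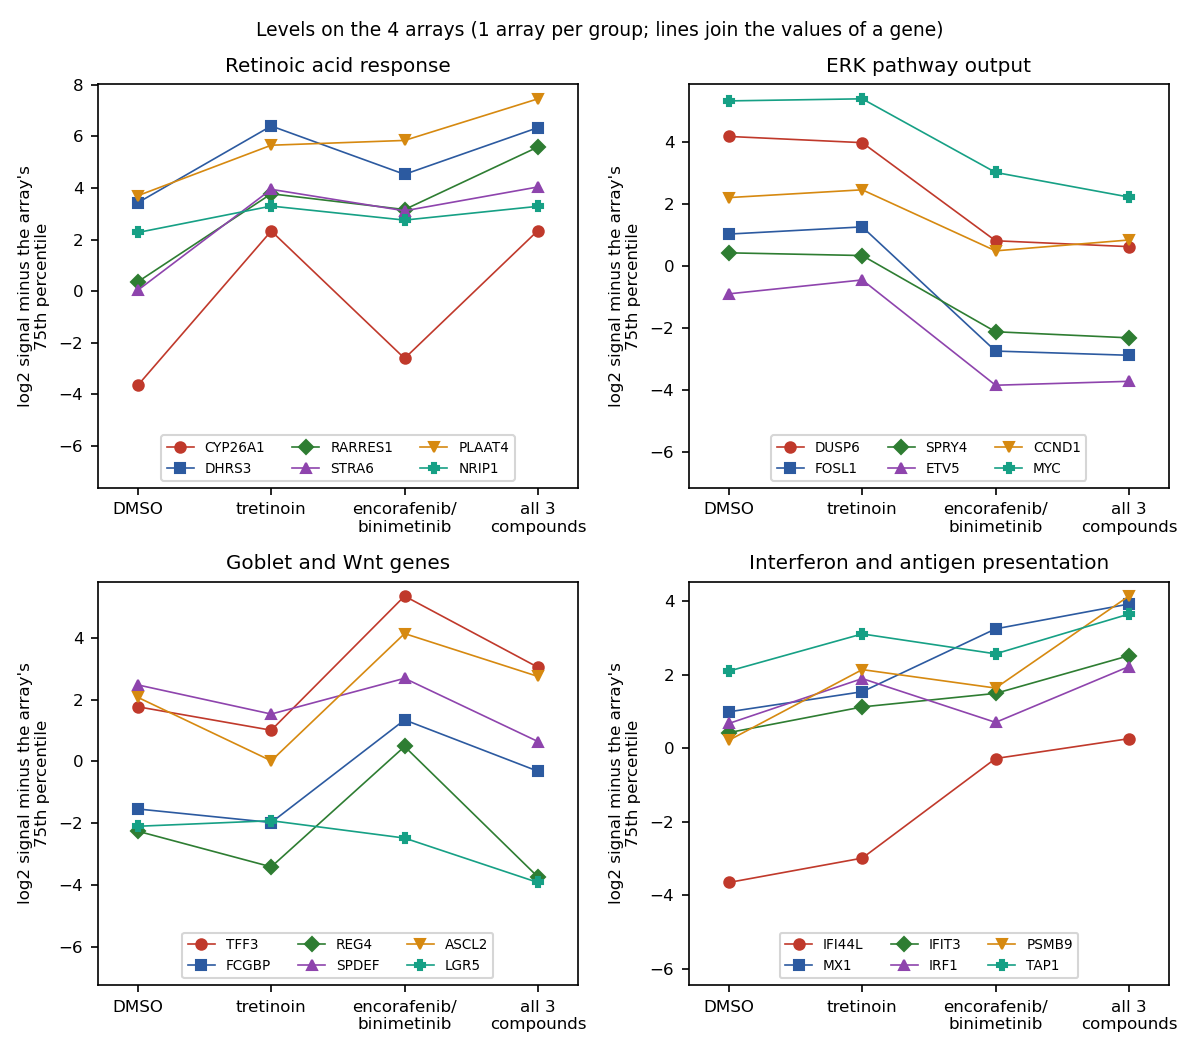
Level of 6 genes in each of 4 panels on the DMSO, tretinoin, encorafenib/binimetinib and all-compound arrays, as log2 signal minus the 75th percentile of the array; each point is 1 array. CYP26A1 was 63.4-fold above DMSO with tretinoin, DUSP6 10.3-fold below DMSO with the inhibitors, and TFF3 12.0-fold above DMSO with the inhibitors.

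Tretinoin was then compared with its absence in the presence of the inhibitors, with no array shared with the first comparison. Outside the dimmest 25% of genes above background on both arrays CYP26A1 was again the highest, 31.1-fold higher (log2 difference 4.96), and as a bound FGF19 was at least 54.1-fold higher. The alcohol dehydrogenase ADH1C was 18.8-fold higher, PIGR, which carries antibodies across the epithelium, 13.5-fold, the cytoskeletal protein SHROOM1 10.1-fold and the receptor ADGRG7 9.13-fold. RAMP1 was 8.36-fold higher, the antimicrobial peptide LEAP2 7.49-fold (log2 difference 2.90, against 0.87 in its other probe), CDX2 6.15-fold and TXK 5.99-fold. HAT1 was 6.23-fold higher, which rests on the same spot with raised local background.

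With the same limits, the genes named by size as lower with tretinoin in the presence of the inhibitors included AQP1 (28.6-fold, a log2 difference of −4.84 against −1.43 in its other probe), the protease KLK12 (20.9-fold), the goblet cell lectin REG4 (18.7-fold) and LY6D (12.9-fold). The intestinal surface antigen GPA33 was 10.4-fold lower, the alkaline phosphatase ALPG 10.3-fold, MGAT3 9.43-fold, the vasoconstrictor EDN2 7.96-fold and BAIAP2L2 7.76-fold. In all, 335 of 18050 genes were at least 2-fold higher, 82 as bounds, and 433 lower, 92 as bounds. The higher share was 43.6%, against 14.3% with spike-in scaling (153 higher and 920 lower), which moved the median of all genes by −0.34 (log2).

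Goblet and enteroendocrine genes stood lowest among the lists, with a median of −1.66 (percentile 0) and 6 of 11 genes at least 2-fold lower. Besides REG4, SPINK4 was at least 26.9-fold lower, TFF2 5.18-fold, TFF3 4.95-fold, SPDEF, a transcription factor of goblet cells, 4.14-fold and FCGBP 3.17-fold, while the mucin MUC2 had a log2 difference of −0.03. Wnt targets and crypt stem cell genes had a median of −0.69 (percentile 0), with 6 of 15 lower, among them CD44 (2.73-fold), the stem cell receptor LGR5 (2.71-fold), ASCL2 (2.62-fold) and AXIN2 (2.24-fold). Enterocyte genes went both ways (median −0.21, percentile 0.92, or 0.095 without a filter on dim genes), with GUCA2A 4.86-fold and FABP1 3.47-fold lower and CDX2 higher. NRF2 targets had a median of −0.30 (percentile 0), with AKR1C1 2.25-fold and AKR1B10 2.18-fold lower. Smaller medians that stood apart on the lower side were −0.19 for cholesterol synthesis (percentile 0.16), −0.18 for the stress response (0.22), −0.16 for MYC and ribosome biogenesis (0.44) and −0.16 for ERK pathway output (0.62).

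Retinoic acid response genes had a median of 0.51 in the presence of the inhibitors (percentile 100, or 0.16 with spike-in scaling). Of 14 genes, 4 were at least 2-fold higher and 1, the binding protein CRABP2, was 2.33-fold lower. DHRS3 was 3.51-fold higher, RARRES1 5.38-fold and PLAAT4 3.06-fold. NF-kB and chemokine genes had a median of 0.77 (percentile 100), with CXCL3 2.29-fold and CXCL8 2.08-fold higher among 12 measured. Antigen presentation had a median of 0.54 (percentile 100, or 0.19 with spike-in scaling). In it 5 of 13 were higher, including PSMB9 (5.67-fold), PSMB8 (2.36-fold), TAP2 (2.28-fold) and TAP1 (2.12-fold). Interferon response genes had a median of 0.44 (percentile 100, or 0.093 with spike-in scaling), with XAF1 2.95-fold, IRF1 2.87-fold and IFIT3 2.04-fold higher among 26. DNA replication (median 0.17) and mitosis (0.13) stood apart on the higher side with no gene past 2-fold, and both medians were negative with spike-in scaling (−0.18 and −0.22). The other lists did not stand apart: retinoid metabolism and RXR (−0.02), the EGFR family (0.01), cell cycle inhibitors (−0.03), pro-apoptotic (0.02) and anti-apoptotic (−0.13) BCL2 members, death receptors and caspases (−0.10), p53 targets (0.04), AHR and PXR targets (−0.01), epithelial-mesenchymal transition (−0.08), non-epithelial markers (−0.10) and housekeeping genes (−0.01).

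**Figure D2:**
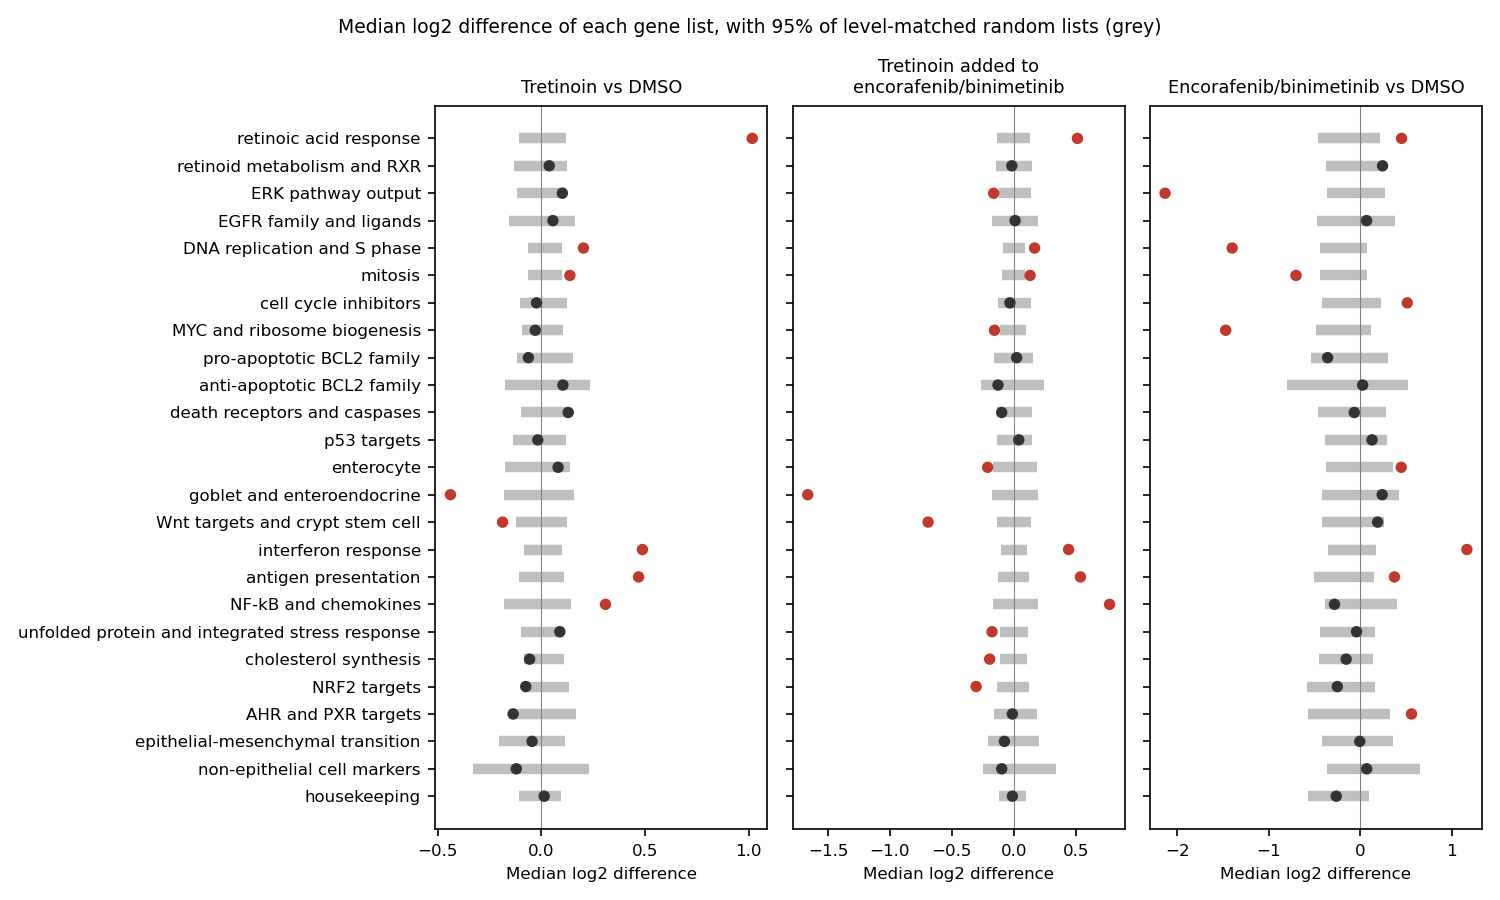
Median log2 difference of each of the 25 gene lists (points) in tretinoin vs DMSO, tretinoin added to encorafenib/binimetinib, and encorafenib/binimetinib vs DMSO; grey bars span 95% of 10000 level-matched random lists and red marks medians outside the percentile range for lists that do not stand apart. Goblet genes lay at −1.66 with tretinoin added to the inhibitors and ERK pathway output at −2.13 with the inhibitors.

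The study's stated question was whether the genes that respond to tretinoin differ with and without encorafenib/binimetinib. Among 17018 genes counted in both tretinoin comparisons, 225 were at least 2-fold higher without the inhibitors and 253 with them, and 95 were in both sets, against 3.35 if the sets were independent. On the lower side the sets held 153 and 370 genes and shared 89, against 3.33. Only 2 genes were higher without and lower with the inhibitors, against 4.89, and 2 the other way, against 2.28. A log2 difference of at least 0.5 in the same direction was found in the other background for 67 of the 130 genes higher only without the inhibitors and 58 of the 158 higher only with them. The same held for 27 of the 64 genes lower only without the inhibitors and 113 of the 281 lower only with them. Across the 16030 genes measured on all arrays, Pearson's r between the tretinoin responses was 0.508 and Spearman's rho 0.347. This correlation is across genes, which are not independent replicates. Without a filter on dim genes r was lower, and the numbers of shared genes changed with that filter and with the normexp correction, as given below.

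The difference between the tretinoin responses was at least 2-fold for 347 of 16030 genes, 139 with a higher and 208 with a lower response in the presence of the inhibitors. Retinoic acid response genes had a lower response with the inhibitors, with a median difference of −0.53 (percentile 0), 3 of 14 past 2-fold and none the other way. With spike-in scaling this median was −1.31. STRA6 was 15.1-fold higher with tretinoin alone and 1.90-fold higher with tretinoin added to the inhibitors, a 7.93-fold difference. Its other probe gave a log2 difference of 2.64 with tretinoin alone, against 3.91, and of −1.99 between the responses, against −2.99. The inhibitors alone had placed this gene 8.46-fold above DMSO, and its level with all compounds was 1.07-fold that with tretinoin. The list as a whole had a median of −0.12 (percentile 49.0) in the comparison of all compounds with tretinoin. Goblet genes had a median difference of −1.11 (percentile 0), with 6 of 10 past 2-fold, and Wnt and stem cell genes one of −0.41 (percentile 0), with LGR5 past 2-fold. In all compounds vs tretinoin, neither list stood apart: the goblet median was −0.38 (percentile 5.14) and the Wnt median 0.09 (percentile 79.6). High readings of these genes on the encorafenib/binimetinib array alone would also lower the difference between the responses. ERK pathway output (−0.22), the stress response (−0.20), death receptors and caspases (−0.22) and NRF2 targets (−0.22) also stood apart on the lower side, with no gene past 2-fold.

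By size, outside the dimmest 25% of genes, those with a lower tretinoin response in the presence of the inhibitors were KLK12 (10.5-fold), ALPG (8.36-fold), the water and glycerol channel AQP3 (8.03-fold), STRA6, the keratin KRT13 (6.74-fold), AQP1 (6.37-fold), CLDN2 (6.15-fold), MGAT3 (4.60-fold), NR0B2 (4.50-fold) and HES6, a relative of the Notch effectors (4.18-fold). The other probe of AQP1 gave a log2 difference of −0.63 against −2.67, and 3 other probes of HES6 gave −1.56, −1.46 and −0.46 against −2.06. KLK12, ALPG, KRT13, AQP1, MGAT3 and HES6 were higher with the inhibitors than with DMSO and lower with tretinoin added to the inhibitors. Both comparisons, and the difference by which these genes were picked, use the encorafenib/binimetinib array. A high reading on that array alone would give differences in these directions. KLK12, ALPG, KRT13 and MGAT3 had no other probe above background. The genes with a higher response were HAT1 (5.97-fold), LEAP2 (4.02-fold), ERVMER34-1 (2.87-fold), SPEF1 (2.85-fold), SHROOM1 (2.84-fold), RASSF10 (2.84-fold), CCNO (2.74-fold), the ubiquitin ligase RNF125 (2.68-fold), TGFBI (2.67-fold) and the centrosomal protein CEP192 (2.62-fold). The other probe of LEAP2 gave 0.95 against 2.01. HAT1, ERVMER34-1, TGFBI and CEP192 were lower with the inhibitors than with DMSO and higher with tretinoin added to the inhibitors. A low reading on the encorafenib/binimetinib array alone would give differences in these directions. The spots of HAT1, ERVMER34-1, CEP192 and NR0B2 on the encorafenib/binimetinib array lay where the local background was between 1.54 and 2.75 times the median of the array. With such spots left out, ERVMER34-1 had a difference of −0.053 from another probe and the other 3 had no value. Against 1.52 for the probe named, the 3 other probes of ERVMER34-1 gave −0.72, −0.43 and −0.05.

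These 347 genes split into 40.1% with a higher and the rest with a lower response. With spike-in scaling, which moved the median of all genes by −0.78 (log2), 9 had a higher and 3347 a lower response, and with the normexp correction 35 and 92. Without a filter on dim genes the majority turned, with 1515 higher and 1354 lower.

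**Figure D3:**
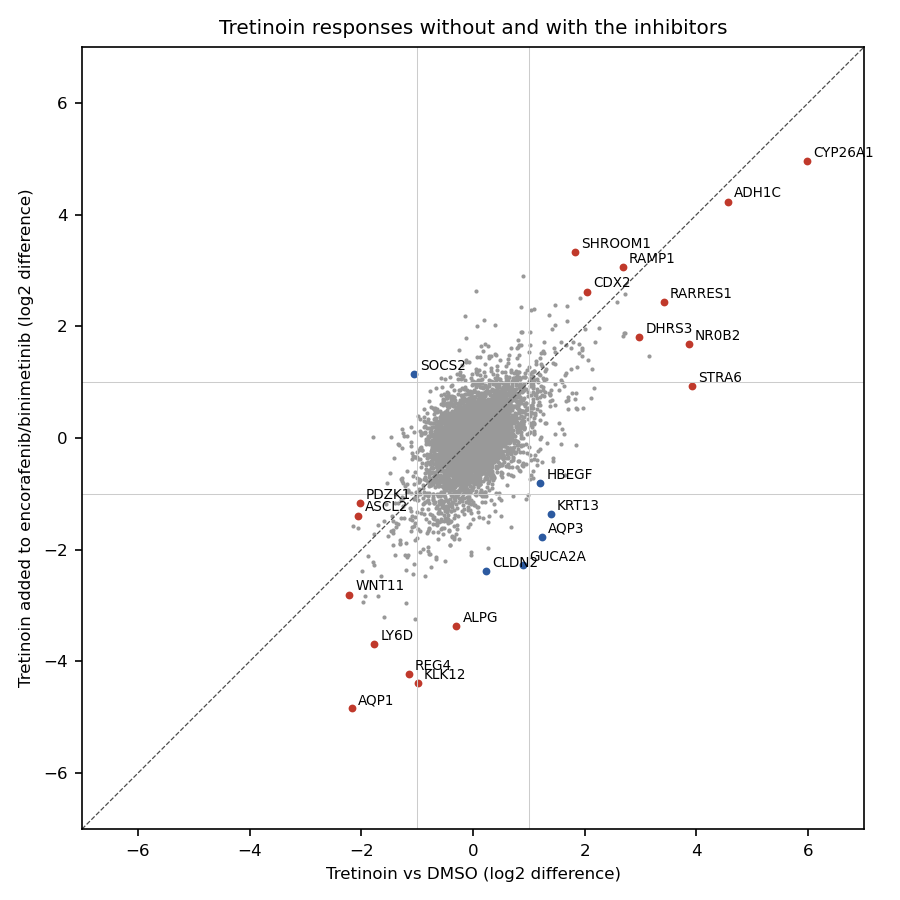
Log2 difference with tretinoin vs DMSO (x axis) against that with tretinoin added to encorafenib/binimetinib (y axis) for 16030 genes measured on 4 arrays; the dashed line marks equal responses, grey lines mark 2-fold, and named genes are red when both responses have the same sign and blue when they do not. CYP26A1 lay at 5.99 and 4.96, and AQP3 at 1.23 and −1.77.

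The inhibitors were compared with their absence in the presence of tretinoin, to set beside their effect without it. DUSP6 was 10.2-fold and FOSL1 17.6-fold lower than with tretinoin alone, and CLDN2 66.3-fold lower. Of 17627 genes, 1694 were at least 2-fold higher and 1411 lower, or 1253 and 2146 with spike-in scaling, which moved the median of all genes by −0.20, and 814 and 1021 with the normexp correction. ERK pathway output had a median of −2.18 and DNA replication of −1.52, each at percentile 0. Among 17315 genes counted in both inhibitor comparisons, 1581 and 1651 were higher, of which 1212 were shared against 150.8 if independent, and 1210 and 1403 were lower, of which 950 were shared against 98.0. Pearson's r between the inhibitor responses across the 16030 genes was 0.887 and Spearman's rho 0.850.

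All 3 compounds were compared with DMSO to describe the combined state. Of 18011 genes, 1917 were at least 2-fold higher and 1444 lower, or 2587 and 878 with spike-in scaling, which moved the median of all genes by 0.21. With the normexp correction the majority turned, with 956 higher and 995 lower. CYP26A1 was 64.1-fold above DMSO and ADH1C 249-fold. Their DMSO signals, 22.9 and 17.4, were near 10.6, the lowest signal well above background on that array, so the size of these folds is uncertain. In the interferon response list 20 of 26 genes were at least 2-fold higher and none lower (median 1.58, percentile 100), and in antigen presentation 5 of 13 (median 0.91, percentile 100). Retinoic acid response genes had a median of 0.88 (percentile 100). ERK pathway output stayed far below DMSO, with 15 of 18 genes lower (median −1.98, percentile 0).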

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

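All tests in this part were chosen after the results were seen, and with 1 array per group the differences between groups named here were not tested against replicates.

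In 9 genes the tretinoin response pointed opposite ways without and with the inhibitors, with each response at least 5 times the technical SD. They were taken from the named and listed genes measured on all arrays, plus SOCS2, which was 2-fold apart in both directions. That error covers repeated spots only, while different probes of a gene differed by an SD of 0.24 in tretinoin vs DMSO and 0.23 with the inhibitors. Across genes measured on both arrays, the log2 differences had an SD of 0.34 in tretinoin vs DMSO and 0.42 with the inhibitors. Responses of the size of EGR1 below are therefore not unusual, and the number of all genes past this bar is not given. Over 17018 genes, those past 2-fold in opposite directions were no more than independent sets give: 2 against 4.89 expected and 2 against 2.28. AQP3 was 2.35-fold higher with tretinoin alone and 3.42-fold lower with tretinoin added to the inhibitors, a log2 difference between responses of −3.01. KRT13 was 2.62-fold higher and 2.57-fold lower (−2.75). The intestinal hormone GUCA2A had log2 differences of 0.90 and −2.28 (−3.18), and the EGFR ligand HBEGF of 1.20 and −0.81 (−2.01). The retinol dehydrogenase RDH12 had 1.23 and −0.43 (−1.67), ZEB1, a regulator of epithelial-mesenchymal transition, 0.89 and −0.51 (−1.40), and the immediate early gene EGR1 0.41 and −0.53 (−0.94). The signal inhibitor SOCS2 had −1.05 and 1.14 (2.19), and RASSF10 −0.41 and 1.09 (1.51).

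The processed signals of some spots exceeded those on the other 3 arrays by over 5 log2 units. There were 16 such spots on the encorafenib/binimetinib array, 13 of them in the last 2 of its 164 columns and 15 marked as outliers by the scanner software. There were 11 on the array with all compounds, 5 of them so marked, 3 on the tretinoin array and 2 on the DMSO array. Spots marked as outliers were left out of the main values. They were not left out of the authors' table or of the patch spots weighed below.

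The first pattern weighed was the place of named genes in a patch of raised local background on the encorafenib/binimetinib array, which held 113 spots at 1.5 times the median local background or more. The array with all compounds had 118 such spots and the others 0. On it, 34.0% of 47 such spots above background on all arrays lay at least 2-fold from the median of the other arrays. Elsewhere on it the share was 13.1% (percentile 99.99 of random sets of as many spots). On the encorafenib/binimetinib array, the share was 35.8% of 53 patch spots, against 11.2% elsewhere. That is at percentile 100.0 of random sets of as many spots. Probes are not placed by function, so this argues against an inhibitor response of the patch genes as a set and is consistent with a fault of the array surface, though single genes in it may respond as well.

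The second pattern was the set of 347 genes with a tretinoin response at least 2-fold different with the inhibitors. The 15 higher genes outside patches that had other probes showed a median signed difference of 0.83 in those probes, and the 35 lower genes 0.98. The other probes had the same sign in 14 of the 15 and 28 of the 35 genes, with first quartiles of 0.49 and 0.20. This argues against faults of single spots as the cause in most of these genes, but not in those whose other probes differ little or point the other way. For the 295 genes with no other probe above background this stays open. No single shift of the arrays left less than 98.8% of the 347 genes in number. The scaling had already centred the differences (median 0.0058), so a shift mostly trades higher for lower genes. The test could hardly have come out otherwise. It shows only that no single shift removes the higher and the lower genes at once, and the split between them depends on the scale. An effect of the inhibitors on the tretinoin response and a difference between single cultures cannot be told apart with 1 array in a group.

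The third pattern was that interferon response and antigen presentation genes were higher both with tretinoin and with the inhibitors. The lowest of the 4 list percentiles was 99.9. The lists were picked because they stood apart in these comparisons, and a shift of an array's scale would move the random lists as much. The outcome was thus set in advance. It shows only that a shift does not set these lists apart from other genes. Both comparisons use the DMSO array, on which a low level would raise both. In the comparisons without it, the interferon medians were 0.44 with tretinoin added to the inhibitors and 1.34 with the inhibitors added to tretinoin. The antigen presentation medians were 0.54 and 0.41. The lowest percentile of the 2 lists was 99.92, so a low DMSO array alone does not account for the pattern. Both of these comparisons use the array with all compounds, however, on which a high level would raise both. A low DMSO array together with a high array with all compounds stays open. With spike-in scaling, tretinoin added to the inhibitors gave medians of 0.093 for interferon response and 0.19 for antigen presentation. How far these lists were higher therefore depends on the scale. Differences between single cultures, such as in density, stay open, as does an effect of each treatment.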

How the results depend on the processing

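The results were recomputed under the 8 alternatives chosen in advance and under the omission of spots with raised local background, chosen after the data were seen. Of the 16 counts and correlations, all 16 stayed within 1.5 times, or within their tolerance, under quantile normalization, scaling by the median of detected probes and the omission of raised-background spots, as did the 12 that the filter on both arrays could give. Counts below are given as higher then lower, in the order tretinoin vs DMSO, tretinoin added to the inhibitors, inhibitors vs DMSO. The normexp correction, whose offset of 50 draws dim signals together, gave 105 and 34, 125 and 181, and 768 and 797. It gave 814 higher for the inhibitors added to tretinoin, 956 higher for all compounds vs DMSO, and 35 and 92 for the difference of the tretinoin responses. The shared tretinoin genes were 45 and 25, the retinoic acid medians 0.78 and 0.40, and the ERK median −1.46. Spike-in scaling gave 778 and 50, 153 and 920, 4175 and 300, then 2146 lower for the inhibitors added to tretinoin, 878 lower for all compounds vs DMSO, and 9 and 3347 for the difference of responses. It gave 37 shared lower genes, retinoic acid medians of 1.45 and 0.16, and an ERK median of −1.56. It reversed the medians of DNA replication (−0.18) and mitosis (−0.22) with tretinoin added to the inhibitors and of Wnt targets with tretinoin vs DMSO (0.24), since it adds a constant to each array. The other 97 of the 100 list medians moved by more than the technical SD of a single gene's difference. That is a wider bar than the technical error of a list median. Of the 100 medians, 30 changed sign, of which only those 3 had stood apart from random genes. The goblet median with tretinoin vs DMSO went from −0.44 to −0.0099. List medians moved by more than that single-gene SD, besides those that reversed, in 26 of 100 under normexp and 22 without a filter. The number was 19 under quantile normalization, 18 under the mean of probes and 6 of 75 under the filter on both arrays. Without a filter the counts were 829 and 850, 1077 and 1085, 2679 and 1918, then 2728 higher for the inhibitors added to tretinoin, 2940 higher for all compounds vs DMSO, and 1515 and 1354 for the difference of responses. Shared genes were 193 and 197, r was 0.241 for the tretinoin and 0.676 for the inhibitor responses, the retinoic acid medians were 0.55 and 0.33 and the ERK median −1.96. The enterocyte median with tretinoin added to the inhibitors reversed to 0.095 and the goblet median with tretinoin vs DMSO to 0.018, with more genes counted. The mean of probes gave an ERK median of −1.70, and the cause was not tested. The values of the authors gave 353 lower genes for tretinoin vs DMSO, against 163 as reported. They were counted without the replacement of values below background. All 80 named gene results, which rest on values above background, stayed within their technical error with them. Over genes above background on all arrays, the difference of responses gave 135 higher and 213 lower, against 139 and 208. Values below background are thus the likely source of the rise to 353. Genes above background on both arrays were not counted separately with the authors' values. Without raised-background spots ERVMER34-1 reversed to −0.053, since another probe then represents it; 73 of the 80 named gene results stayed within their technical error, and HAT1, CEP192 and NR0B2 had no value. Named gene results moved by more than that error, in the same direction, in 53 of 80 under quantile normalization, 63 under normexp, 80 under spike-in scaling and 20 under the mean of probes. No paired analysis was possible because each group had 1 array, all numbered replicate 1, so the numbers pair nothing. An additive fit over both backgrounds would leave 1 residual degree of freedom and was not run. Between 48.6% and 52.2% of spots were well above background per array, so genes below it have bounds or no value.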

Other observations

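The tests in this part were chosen after the results were seen, and so were the genes named, except those of the fixed lists.

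Averaged over both backgrounds, genes past 2-fold with tretinoin, in either direction, overlapped those higher with the inhibitors. Both averages use the same arrays. A gene high on the encorafenib/binimetinib array alone therefore counts as lower with tretinoin and higher with the inhibitors. A gene high on the array with all compounds alone counts as higher with both. The overlaps can thus exceed those of independent sets without a separate response to each treatment. Of 16030 genes measured on all arrays, 140 were at least 2-fold higher with tretinoin and 1190 with the inhibitors, and 56 were both, against 10.4 if independent. A further 56 were lower with tretinoin and higher with the inhibitors, against 10.8, while 10 were higher with tretinoin and lower with the inhibitors and 9 lower with both, against 10.0 and 10.4. Genes higher with both included ADH1C (averaged log2 differences of 4.40 with tretinoin and 3.57 with the inhibitors), the bile acid receptor NR1H4 (1.28 and 3.71), the iron-binding protein LCN2 (1.71 and 1.26) and the antiviral sensor TLR3 (1.71 and 2.08). Genes lower with tretinoin and higher with the inhibitors included the mucin MUC1 (averaged log2 differences of −1.57 and 2.62), the brush border myosin MYO1A (−2.39 and 1.28), LGALS2 (−1.49 and 2.03) and PHGR1 (−2.26 and 2.25). MYO1A was 4.25-fold higher with the inhibitors vs DMSO but 1.39-fold higher with the inhibitors added to tretinoin.

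Single genes known from bile acid metabolism had these values. NR1H4 was 31.7-fold above DMSO with all compounds, and the bile acid transporter subunit SLC51A 12.0-fold above DMSO with the inhibitors. FGF19, a target of NR1H4, was 6.98-fold above DMSO with tretinoin, at least 66.6-fold below DMSO with the inhibitors and 1.23-fold below DMSO with all compounds. FGF19 was read by 1 spot on each array. SLC51B had a log2 difference of 0.39 with the inhibitors and FABP6 of 0.22.

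Single genes known for their response to interferon, outside the fixed lists and picked because they were higher with both treatments, had these values. SAMD9L was 2.96-fold higher with tretinoin vs DMSO and 5.85-fold with the inhibitors vs DMSO, RTP4 3.22-fold and 5.49-fold, and GBP4 2.14-fold and 1.98-fold.

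A hypothesis was that the interferon and antigen presentation genes with the largest response to the inhibitors are also those with the largest response to tretinoin, each averaged over both backgrounds. Across the 12 antigen presentation genes r was 0.777 (95% interval 0.367 to 0.934, Spearman's rho 0.762), so members such as PSMB9 may answer to both. Both averages use the same arrays, however. Values high on the array with all compounds alone, or low on the DMSO array alone, would also raise r. Across the 25 interferon response genes r was 0.102 (interval −0.305 to 0.478, rho 0.229), an interval too wide to decide for that list. IRF1 was 2.33-fold higher with tretinoin vs DMSO and 1.02-fold with the inhibitors vs DMSO, while IFI44L was 1.58-fold and 10.4-fold higher. The intervals treat genes as independent, which they are not, and across all 16030 genes r was 0.0804.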
